A study of Macaca mulatta with 24 samples.

How the data were processed

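Total RNA from 24 dissected pieces of rhesus monkey neocortex was labelled with biotin and hybridised to 24 one-colour Affymetrix Rhesus arrays, one array per piece, per the labels' protocols. The pieces covered M1, PMd, PMv and A46 in both hemispheres of 3 animals, and each was assigned to its area, hemisphere and animal from its title. The deposited values are array intensities on a linear scale, summarised per probe set with RMA (robust multi-array average), per the submitters' processing notes. The version of RMA and the set of arrays normalised together are not given in the sources used here. Median intensity was 47.9 to 51.6 per array. Because RMA brings arrays to a common distribution, a shift of all transcripts together in one area cannot be seen in these values, and differences are relative to the other transcripts of the same array. Microarray data have no read depth, and the number of animals, 3, limits the precision.

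The intensities were converted to log2, and 0 values lay below the floor of 1 that had been set. Of 52865 probe sets, 99 controls were removed. The remaining 52766 comprised 24956 with 1 gene symbol, 361 with several and 27449 with none, naming 14132 genes. Of the 24956, 24616 matched a current gene entry by Entrez ID, and 0 symbols needed updating. The deposited values and their annotation name no genome build, so no coordinates are given. Probe sets with a mean log2 value below the median of all, 5.62 (intensity 49.3), were left out, which kept 26383 for the tests. A gene with several probe sets was represented by the one with the highest mean, giving 10043 genes.

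The animal was the replicate. The 2 hemispheres of each animal and area were averaged, giving 12 means (3 per area), and limma (version 3.58.1, R 4.3.3) was fitted with lmFit and eBayes with an intensity trend, with area and animal as terms. All 4 areas shared one estimate of the spread, with 6 residual and 6.98 prior degrees of freedom. The animal was kept as a block in the main model because every area came from the same 3 animals. The numbers in the titles were checked as pairs. After the area means were removed, the 18 pairs of means from one animal correlated at 0.207 to 0.85 (median 0.605), and the 36 pairs from different animals at -0.561 to 0.065. Removing means over 3 animals itself pushes the values between different animals below 0, so the check rests on the positive values within animals. The contrasts were the mean of the motor areas (M1, PMd and PMv) minus A46, M1 minus A46, M1 minus the mean of both premotor areas, the other pairs of areas, and an F test for any difference between areas. Left minus right was tested on the 24 arrays with each animal-by-area pair as a block (11 residual degrees of freedom). These 12 pairs come from 3 animals and were treated as independent, so the p-values of this test rest on more units than animals, and a fit on per-animal means was run as an alternative. An F test asked whether it differed between areas. Benjamini-Hochberg adjusted p-values under 0.05 within a contrast were called. Tests were two-sided. The adjusted p-values for single genes below all come from limma.

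Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, in 5 comparisons, and Benjamini-Hochberg adjustment covered all 115 tests. The 23 tested lists were layer 4 and granular cortex markers, upper layer markers, layer 5 and corticospinal markers, layer 6 and subplate markers, neurofilament and large projection neuron genes, fast-firing ion channel genes, GABAergic interneuron markers, glutamatergic transmission genes, GABA receptor genes, monoamine and acetylcholine receptor genes, genes enriched in primate association cortex, genes enriched in primate motor or sensory cortex, axonal growth and plasticity genes, axon guidance and adhesion genes, cortical patterning and retinoic acid genes, immediate early genes, mitochondrial respiration genes, oligodendrocyte and myelin genes, and markers of astrocytes, microglia, endothelial cells and pericytes, meninges and choroid plexus, and striatal neurons. The neurofilament, association-cortex and motor or sensory-cortex lists shared 3, 4 and 5 of their tested genes with other lists, and these are counted in each. A list of blood cell genes had 3 tested genes, under the minimum of 5, and is described without a test. A list of sex chromosome genes meant as a check of the animal labels had 0 genes named on the array, so that check was void.

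Genes were named by a rule. For motor areas minus A46, M1 minus A46 and M1 minus premotor the rule took up to 10 genes each way with the largest log2 differences among those past the threshold and changed the same way in all 3 animals. For every other comparison it took up to 4 each way. Each list contributed up to 4 members with the smallest p, and 18 genes were fixed by name, of which NEFM, GDF7, CALB1 and SCN4B have no probe set naming them here and BCL11B lay below the intensity filter. Design, rule, lists and alternatives were fixed before the data were examined, apart from the alternatives and tests named in the closing section as chosen later.

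The fits were tested on simulated data with the size and spread of the real set. With 100 of 26383 probe sets changed 1.5-fold and 100 changed 2-fold in M1, M1 minus A46 recovered 95% of the 1.5-fold and 100% of the 2-fold changes with 14 unchanged probe sets called, and M1 minus premotor recovered 98% and 100% with 8 unchanged called. With the same numbers changed in the left hemisphere, left minus right recovered 100% at both sizes with 8 unchanged called. With no change simulated, 0 probe sets were called in any of the 8 area contrasts. Simulated probe sets vary independently and real ones do not, so real error rates may differ.

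Alternatives covered the intensity filter (none, or the top 25% kept), the trend, cyclic loess between arrays, the animal block, hemispheres as samples, single hemispheres, fits on only the areas compared, per-animal means, each animal left out, and for the lists an estimated correlation and the mean of all probe sets of a gene. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Scanner-level data were not analysed here.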

Results

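Gene expression was compared among 4 areas of the neocortex of adolescent rhesus monkeys (Macaca mulatta): the forelimb region of primary motor cortex (M1), dorsal and ventral premotor cortex (PMd and PMv), and prefrontal area 46 (A46). Each area was dissected from both hemispheres of 3 group-caged animals without experimental treatment, 2 males and 1 female aged 2.6 to 2.7 years, giving 24 arrays, 6 per area. Animals 1 and 2 were the males and animal 3 the female, so fits without animal 3 hold males only. The log2 values of any 2 arrays correlated at 0.978 to 0.997 across probe sets, and the largest number of identical values shared by a pair of arrays was 126 of 52865, so no array was a copy of another. The series sets motor against prefrontal areas, and the question of each comparison was which transcripts differ between them. Effects are log2 differences of area means over 3 animals, with limma's standard error (SE).

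NEFH, the neurofilament heavy chain of thick axons, had a mean log2 intensity of 8.98 in A46, 9.95 in PMv, 10.4 in PMd and 11.22 in M1, and SPP1, which encodes osteopontin, one of 8.06, 9.14, 9.37 and 10.34. An F test over all 4 areas called 1723 of 26383 probe sets, naming 948 genes. Of the variance of the 12 animal-by-area means, area accounted for 29.1%, animal for 48.3% and the remainder for 22.6%. The count of calls for any area difference was 609 without animal 1, 129 without animal 2 and 7754 without animal 3, and 288 with the animal left out of the model.

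**Figure D1:**
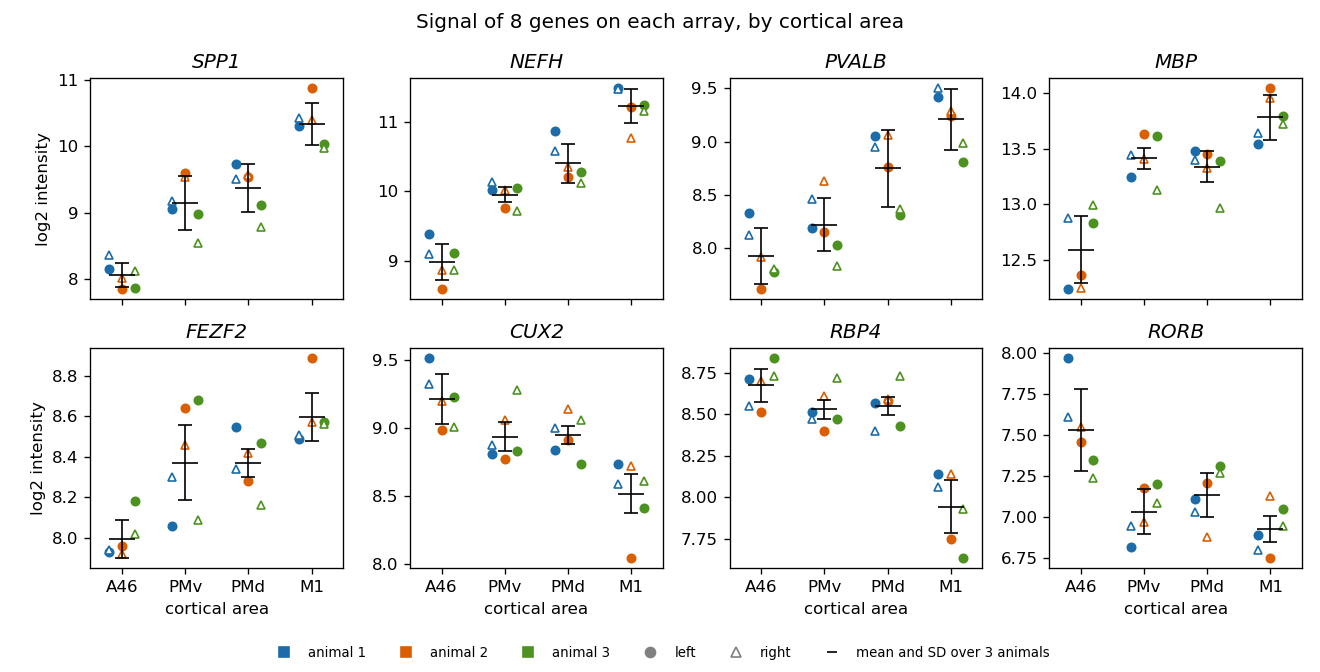
Log2 intensity (vertical axis) of 8 genes on each of the 24 arrays, by cortical area (horizontal axis); colour marks the animal, filled circles the left and open triangles the right hemisphere, and bars the mean and SD over 3 animals. SPP1, NEFH, PVALB, MBP and FEZF2 have their highest mean in M1 and their lowest in A46, and CUX2, RBP4 and RORB the reverse.

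M1 was first set against A46. RFTN2, a lipid-raft protein gene, was 5.16-fold higher in M1 (log2 difference 2.37, SE 0.12, adjusted p = 4.58e-07). SPP1, which encodes the secreted phosphoprotein osteopontin, was 4.84-fold higher (2.27, SE 0.13, adjusted p = 1.37e-06), with a log2 intensity of 10.34 ± 0.31 in M1 and 8.06 ± 0.18 in A46 (SD, n = 3 animals). UGT8, the enzyme that makes the myelin lipid galactosylceramide, was 4.8-fold higher (2.26, SE 0.2, adjusted p = 2.5e-05). NEFH, the neurofilament heavy chain of thick axons, was 4.72-fold higher (2.24, SE 0.08, adjusted p = 1.14e-08), at 11.22 ± 0.24 in M1 and 8.98 ± 0.26 in A46 (SD, n = 3 animals). The other genes with the largest rises were LOC699434 (2.09), EVI2A (2.07), SPMIP7 (1.99), the peroxisomal carrier SLC25A17 (1.98), the actin-binding protein ANLN (1.95) and the sodium-calcium exchanger SLC8A1 (1.84).

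The genes furthest below A46 in M1 were FREM3, an extracellular matrix protein (-1.37, SE 0.11, adjusted p = 1.03e-05), and EPHA3, an ephrin receptor of axon guidance (-1.34, SE 0.08, adjusted p = 1.72e-06). ANKRD6 (-0.98), the nociceptin receptor OPRL1 (-0.96), ST14 (-0.95), SH2D4B (-0.93), the secreted protein TAFA1 (-0.92), SLF1 (-0.9), the troponin TNNT2 (-0.89) and the leukocyte tetraspanin CD53 (-0.88) followed. Of 3 tested probe sets for ST14 only 1 had this sign, and of 3 for CD53 all had it and 2 passed. All 20 of these genes changed the same way in 3 of 3 animals, which the naming rule required, and all passed with any 1 animal left out.

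Myelin and large-neuron genes were higher in M1. Of 9 tested oligodendrocyte and myelin genes, 8 rose and CNP did not pass (-0.08, adjusted p = 0.576), and 8 passed when adjusted over the list alone. PLLP (1.55, SE 0.16), ENPP2 (1.32, SE 0.14) and SOX10 (1.23, SE 0.12), the transcription factor of oligodendrocytes, rose with myelin basic protein MBP (1.19, SE 0.13, adjusted p = 9.91e-05). The list's median was 1.23 (camera adjusted p = 3.96e-09). Of 8 neurofilament and large projection neuron genes 5 rose (5 when adjusted over the list alone), led by NEFH and SPP1 and including the synaptic vesicle protein VAMP1 (0.74, SE 0.07), with a median of 0.24 (camera adjusted p = 7.18e-05). Of 6 genes enriched in primate motor or sensory cortex 3 rose (3 when adjusted over the list alone), namely NEFH, SPP1 and the calcium-binding protein PVALB (1.28, SE 0.1, adjusted p = 1.03e-05), with a median of 0.69 (camera adjusted p = 0.000767). Each of these lists had an adjusted p = 0.298 with an estimated correlation.

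Genes of fast firing and of respiration were also higher in M1. Of 8 fast-firing ion channel genes 4 rose and 1 fell (5 and 1 when adjusted over the list alone), among them the sodium channel SCN1A (0.87, SE 0.12) and the potassium channels KCNA1 (0.69, SE 0.1), KCNC1 (0.55, SE 0.07) and KCNA2 (0.32, SE 0.08). The list's median was 0.24 (camera adjusted p = 0.0111), with adjusted p = 0.477 with an estimated correlation and 0.149 without animal 3. All 22 mitochondrial respiration genes had a positive difference and 8 rose (12 when adjusted over the list alone), such as COX7B (0.48, SE 0.08) and ATP5F1C (0.38, SE 0.06), with a median of 0.18 (camera adjusted p = 2.51e-06). That list had an adjusted p = 0.371 with an estimated correlation. KCNA2 (adjusted p = 0.192), COX7B (0.133) and ATP5F1C (0.168) did not pass without animal 2.

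Immediate early genes, whose transcription follows neuronal activity, were lower in M1 than in A46. Of 15 tested, 10 fell (13 when adjusted over the list alone), led by EGR2 (-0.88, SE 0.11), NR4A1 (-0.54, SE 0.08), EGR4 (-0.5, SE 0.09) and KLF10 (-0.48, SE 0.09), with a median of -0.37 (camera adjusted p = 1.45e-08, and adjusted p = 0.298 with an estimated correlation). Of 9 glutamatergic transmission genes 5 fell (8 when adjusted over the list alone), among them GRM7 (-0.73, SE 0.15), GRIK1 (-0.65, SE 0.12), CAMK2A (-0.53, SE 0.14) and GRIA4 (-0.37, SE 0.08), with a median of -0.37 (camera adjusted p = 0.000104, and adjusted p = 0.298 with an estimated correlation). Without animal 2 the adjusted p-values were 0.077 for NR4A1, 0.102 for EGR4, 0.133 for KLF10, 0.133 for GRM7, 0.096 for GRIK1, 0.285 for CAMK2A and 0.277 for GRIA4. GRM7 (0.0673) and CAMK2A (0.163) did not pass without animal 1 either. The log2 ratio of 3' to 5' actin probe sets, a measure of RNA integrity, was 0.94 ± 0.05 in M1 and 1.08 ± 0.11 in A46 (SD, n = 3 animals), and that of GAPDH 0.96 ± 0.04 and 0.84 ± 0.05.

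Upper layer and guidance genes were lower in M1. Of 11 upper layer projection neuron markers 5 fell (5 when adjusted over the list alone), including the transcription factor CUX2 (-0.69, SE 0.09), the protocadherin PCDH8 (-0.67, SE 0.09), C1QL2 (-0.47, SE 0.07) and MEF2C (-0.39, SE 0.07), with a median of -0.18 (camera adjusted p = 0.000591, and adjusted p = 0.432 with an estimated correlation). Of 30 axon guidance and adhesion genes 12 fell and 1 rose (14 and 4 when adjusted over the list alone), with EPHA3, PCDH8, the cadherin CDH8 (-0.65, SE 0.1) and the netrin NTNG1 (-0.65, SE 0.11) leading, and a median of -0.15 (camera adjusted p = 0.000601, and adjusted p = 0.512 with an estimated correlation). C1QL2 (adjusted p = 0.0786), MEF2C (0.141), CDH8 (0.0893) and NTNG1 (0.0854) did not pass without animal 2.

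Layer 5 markers moved both ways. FEZF2, the determinant of subcerebral projection neurons, was higher in M1 (0.61, SE 0.09, adjusted p = 0.000642), while TSHZ2 (-0.81, SE 0.09), RBP4 (-0.73, SE 0.09) and the thyroid hormone-binding protein CRYM (-0.7, SE 0.08) were lower. Of 13 markers 3 rose, 3 fell (4 and 5 when adjusted over the list alone) and the list was not called (median -0.03, camera adjusted p = 0.557). In layer 4 markers 2 of 6 fell, CUX2 and RORB (-0.6, SE 0.12, adjusted p = 0.00489), also when adjusted over the list alone, and the list was not called (median -0.07, camera adjusted p = 0.0733). Of 10 layer 6 and subplate markers 4 rose, led by SYT6 (0.88, SE 0.12), and 0 fell (4 and 1 when adjusted over the list alone; median 0.05, camera adjusted p = 0.184). Of 5 genes enriched in association cortex 3 fell and 0 rose (3 and 1 when adjusted over the list alone), namely RBP4, SLIT1 (-0.57, SE 0.11) and PNMA5 (-0.48, SE 0.08), with a median of -0.48 (camera adjusted p = 0.0927). GAP43 (0.17, adjusted p = 0.288) and the serotonin receptor HTR2A (-0.2, adjusted p = 0.28) did not pass, although the other of 2 GAP43 probe sets passed with the same sign. Without animal 2, FEZF2 (adjusted p = 0.0578), RORB (0.139), SLIT1 (0.23) and PNMA5 (0.172) did not pass, and without animal 1 the layer 4 list (0.0336) and the association-cortex list (0.0282) passed.

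Markers of other cells changed less in M1 than myelin genes did. Of 13 astrocyte markers 2 rose, S100B (0.69, SE 0.14) and ALDOC (0.27, SE 0.05), with a list median of 0.05 (camera adjusted p = 0.475). Of 12 microglia markers 2 rose, TYROBP (0.48, SE 0.11) and ITGAM (0.26, SE 0.06), and CD68 fell (-0.41, SE 0.08), with a median of 0.04 (camera adjusted p = 0.557). Of 8 endothelial and pericyte markers 1 rose, the glucose transporter SLC2A1 (0.24; median 0.05, camera adjusted p = 0.45), of 11 meninges and choroid plexus genes 1, SLC47A1 (0.29; median -0.09, camera adjusted p = 0.354), and of 7 striatal neuron genes 1, PENK (0.25, with this sign in 1 of 2 probe sets; median -0.05, camera adjusted p = 0.529). When adjusted over the list alone these counts were the same, except that 2 striatal genes fell. The 3 tested blood cell genes did not pass (median -0.07). Without animal 2, S100B (adjusted p = 0.128), ALDOC (0.221), TYROBP (0.406), ITGAM (0.459), CD68 (0.204), SLC2A1 (0.394), SLC47A1 (0.201) and PENK (0.496) did not pass. Nor did TYROBP (0.0864), ITGAM (0.0798), CD68 (0.0817), SLC2A1 (0.0881) and SLC47A1 (0.195) without animal 1 or SLC2A1 (0.0508) without animal 3.

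Of the area comparisons M1 minus A46 had the most calls, although without animal 3 PMv minus A46 (7009) and motor areas minus A46 (6463) had more than its 5410. Here limma called 1976 probe sets higher and 1415 lower in M1 than in A46, of which 132 and 14 differed at least 2-fold. For M1 minus A46 the total of 3391 was 1648 without animal 1, 403 without animal 2 and 5410 without animal 3. With the animal left out of the model it was 1056. The majority of higher calls turned over with the spread of log2 values as a covariate (3098 higher and 3421 lower).

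**Figure D2:**
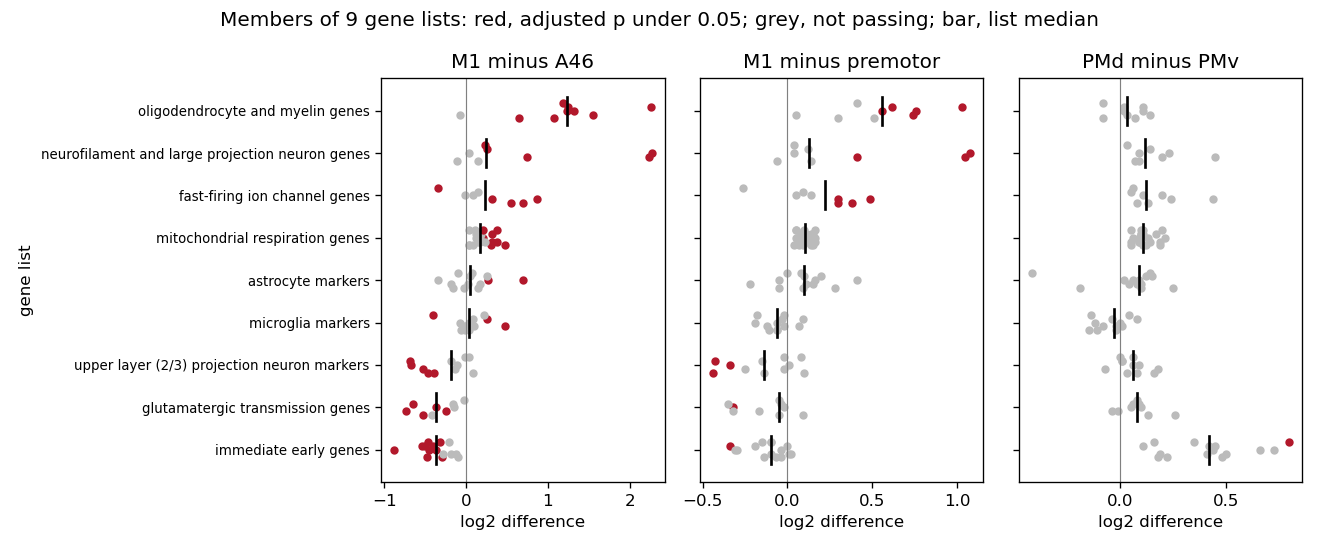
Log2 difference (horizontal axis) of each tested member of 9 gene lists (vertical axis) for M1 minus A46, M1 minus premotor and PMd minus PMv. Points are genes, red where the adjusted p is under 0.05 and grey otherwise, and the bar is the list median; immediate early genes lie at a median of -0.37 in M1 minus A46 and 0.42 in PMd minus PMv.

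The mean of the 3 motor areas showed a smaller difference from A46 in the leading genes. RFTN2 (1.61, SE 0.1), UGT8 (1.58, SE 0.17), SPP1 (1.55, SE 0.11), NEFH (1.54, SE 0.06, adjusted p = 1.01e-07) and SLC8A1 (1.53, SE 0.2) were highest in the motor areas, followed by LOC699434 (1.48), EVI2A (1.43), SPMIP7 (1.41), ANLN (1.39) and SLC25A17 (1.34). FREM3 (-0.76, SE 0.09), EPHA3 (-0.76, SE 0.07), CD53 (-0.75, SE 0.06), TNNT2 (-0.74, SE 0.07) and FSTL5 (-0.71, SE 0.08) were lowest, followed by EGR2 (-0.68), ST14 (-0.68, again with this sign in 1 of 3 probe sets), SLF1 (-0.66), OPRL1 (-0.65) and the actin-capping protein TMOD1 (-0.64). Of the fixed genes PVALB (0.8), MBP (0.92) and FEZF2 (0.45) were higher and CRYM (-0.51), RORB (-0.5), SLIT1 (-0.42), CUX2 (-0.41) and RBP4 (-0.33) lower. PNMA5 (-0.19, adjusted p = 0.0954), HTR2A (-0.13, adjusted p = 0.392) and GAP43 (0.09, adjusted p = 0.5) did not pass, although the other of 2 GAP43 probe sets passed with the same sign. CRH, a neuropeptide of interneurons, was higher by 0.61 (SE 0.08). Without animal 2, SLC8A1 (adjusted p = 0.0661), SLF1 (0.06), FEZF2 (0.132), CRYM (0.0664), RORB (0.211), SLIT1 (0.334), CUX2 (0.114) and RBP4 (0.224) did not pass, nor did RORB (0.0859) and SLIT1 (0.109) without animal 1.

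Among the lists, 8 of 9 oligodendrocyte genes rose in the motor areas (8 when adjusted over the list alone; median 0.83, camera adjusted p = 7.8e-09) and 8 of 15 immediate early genes fell (11 when adjusted over the list alone; median -0.26, camera adjusted p = 1.38e-08), each with adjusted p = 0.298 with an estimated correlation. Of 22 mitochondrial genes 7 rose (8 when adjusted over the list alone; median 0.1, camera adjusted p = 5.66e-05, and adjusted p = 0.438 with an estimated correlation). Neurofilament genes (median 0.19, camera adjusted p = 7.7e-05) and motor or sensory-cortex genes (0.42, 0.000778) were higher as lists, and glutamatergic genes (-0.16, 0.000348) lower, each with adjusted p = 0.298 with an estimated correlation. In that order 5 of 8, 3 of 6 and 4 of 9 genes passed limma's threshold. Upper layer markers (-0.13, camera adjusted p = 0.00139) and axon guidance genes (-0.09, 0.00648) were lower as lists and fast-firing genes (0.11, 0.0362) higher, with adjusted p = 0.438, 0.559 and 0.512 with an estimated correlation. By limma 3 of 11 upper layer markers fell, 9 of 30 axon guidance genes fell and 2 rose, and 3 of 8 fast-firing genes rose. The fast-firing call was lost without animal 3 (adjusted p = 0.393). The totals for motor areas minus A46 were 1389 probe sets higher and 1240 lower. The sum of 2629 was 861 without animal 1, 180 without animal 2, 6463 without animal 3 and 479 with the animal left out of the model. The balance of directions was not stable, with 659 higher and 202 lower without animal 1 and 2511 higher and 3952 lower without animal 3.

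M1 was also set apart from the premotor areas. RFTN2 (1.14, SE 0.11, adjusted p = 0.000664), SPP1 (1.08, SE 0.12, adjusted p = 0.00156), NEFH (1.05, SE 0.07, adjusted p = 2.69e-05) and UGT8 (1.03, SE 0.18, adjusted p = 0.0108) were about 2-fold higher in M1, followed by SLC25A17 (0.97), EVI2A (0.96), TMEM144 (0.93), LOC699434 (0.92), the guanine nucleotide exchange factor DOCK5 (0.91) and SPMIP7 (0.87). FREM3 (-0.91, SE 0.09), EPHA3 (-0.88, SE 0.07), ANKRD6 (-0.61), SH2D4B (-0.6), RBP4 (-0.6), PLAC9 (-0.53), TAFA1 (-0.52), the formin DIAPH3 (-0.5), OPRL1 (-0.47) and TMEM200A (-0.47) were lower. PVALB (0.73, adjusted p = 0.00242) was higher and CUX2 (-0.43, adjusted p = 0.0188), PNMA5 (-0.43, adjusted p = 0.0107) and CRYM (-0.29, adjusted p = 0.0405) were lower. MBP (0.41, adjusted p = 0.106), FEZF2 (0.23, adjusted p = 0.191), SLIT1 (-0.23, adjusted p = 0.341), RORB (-0.15, adjusted p = 0.611), GAP43 (0.11, adjusted p = 0.639) and HTR2A (-0.1, adjusted p = 0.751) did not pass. The other of 2 MBP probe sets passed with the same sign. Without animal 2 the adjusted p was 0.0656 for UGT8, 0.153 for EVI2A, 0.112 for TMEM144, 0.0592 for LOC699434, 0.202 for DOCK5 and 0.107 for SPMIP7. Among the lower genes it was 0.207 for SH2D4B, 0.13 for RBP4, 0.116 for PLAC9, 0.192 for TAFA1, 0.153 for DIAPH3, 0.177 for OPRL1 and 0.375 for TMEM200A. Among the fixed genes it was 0.498 for PNMA5, 0.721 for CRYM and 0.644 for CUX2. UGT8 (0.0522), EVI2A (0.0628), LOC699434 (0.0736) and CRYM (0.11) did not pass without animal 1, nor TMEM200A (0.0619) without animal 3.

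Of 9 oligodendrocyte genes 5 were higher in M1 than in premotor cortex (8 when adjusted over the list alone), including ENPP2 (0.76), PLLP (0.74) and SOX10 (0.56). These 3 had adjusted p = 0.107, 0.181 and 0.348 without animal 2, and PLLP (0.0705) and SOX10 (0.0957) did not pass without animal 1. The list had a median of 0.56 (camera adjusted p = 3.42e-09, and adjusted p = 0.298 with an estimated correlation). In the layer 5 list 5 of 13 markers fell and 1 rose (5 and 2 when adjusted over the list alone; median -0.05, camera adjusted p = 0.00518, and adjusted p = 0.298 with an estimated correlation). The call was lost without animal 3 (adjusted p = 0.0502). All 22 mitochondrial genes had a positive difference, 0 of them past limma's threshold (0 when adjusted over the list alone), with a median of 0.1 (camera adjusted p = 2.44e-05, and adjusted p = 0.432 with an estimated correlation). Neurofilament genes (median 0.13, camera adjusted p = 5.66e-05) and motor or sensory-cortex genes (0.42, 7.7e-05) were higher as lists and layer 4 markers (-0.06, 0.0257) lower, each with adjusted p = 0.298 with an estimated correlation. In these lists 3 of 8, 3 of 6 and 1 of 6 genes passed limma's threshold. Fast-firing genes (0.22, camera adjusted p = 0.00311) and layer 6 markers (0.09, 0.0188) were higher as lists, and upper layer markers (-0.14, 0.00107) and immediate early genes (-0.1, 0.000348) lower, each with adjusted p = 0.438 with an estimated correlation. Here 4 of 8, 1 of 10, 3 of 11 and 1 of 15 genes passed limma's threshold, in that order. Axon guidance (-0.07, camera adjusted p = 5.01e-05), glutamatergic (-0.05, 0.00226) and association-cortex genes (-0.23, 0.0218) were lower as lists, with adjusted p = 0.459, 0.358 and 0.371 with an estimated correlation. Only 2 of 30, 1 of 9 and 2 of 5 of their genes passed limma's threshold, all of them lower. Without animal 2 the calls of layer 4 (adjusted p = 0.0686), layer 6 (0.119) and association-cortex genes (0.109) were lost, and without animal 3 those of layer 4 (0.0523) and layer 6 (0.0771).

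For M1 minus premotor 402 probe sets were higher and 168 lower. The split was 543 and 353 with cyclic loess between arrays, and it turned over to 504 and 583 with the spread of log2 values as a covariate. The sum of 570 was 199 without animal 1, 25 without animal 2, 1370 without animal 3 and 11 with the animal left out of the model. Of the 20 genes with the largest differences 13 did not pass without animal 2, 3 without animal 1 and 1 without animal 3; RFTN2 (adjusted p = 0.0148 without animal 2), SPP1 and NEFH were not among them.

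M1 was also compared with each premotor area separately. SPP1 (0.96, SE 0.13), RFTN2 (0.9, SE 0.12), SLC25A17 (0.87, SE 0.16) and NEFH (0.82, SE 0.08) were higher in M1 than in PMd, and DIAPH3 (-0.95, SE 0.1), FREM3 (-0.92, SE 0.11), EPHA3 (-0.83, SE 0.08) and EGR2 (-0.62, SE 0.11) lower. RFTN2 (1.38, SE 0.12), NEFH (1.27, SE 0.08), SPP1 (1.19, SE 0.13) and UGT8 (1.09, SE 0.2) were higher in M1 than in PMv, and EPHA3 (-0.93, SE 0.08), FREM3 (-0.91, SE 0.11), ANKRD6 (-0.66, SE 0.09) and SH2D4B (-0.61, SE 0.1) lower. RBP4 was lower in M1 than in PMd (-0.61) and PMv (-0.59), and PVALB was higher than in PMv (0.99, adjusted p = 0.000714) and did not pass against PMd (0.46, adjusted p = 0.0778). M1 minus PMd called 45 probe sets higher and 42 lower, a split that turned over to 19 and 31 with no trend in eBayes and to 308 and 360 with the spread of log2 values as a covariate. M1 minus PMv called 371 and 123. With cyclic loess between arrays the split for M1 minus PMv was 433 and 339, and with the spread of log2 values as a covariate 228 and 363. Which premotor area had more calls depended on the fit: with only the areas compared the totals were 1582 against PMd and 1225 against PMv, and with the covariate 668 and 591. Without animal 1 the totals were 33 and 68, without animal 2 they were 0 and 21, and without animal 3 they were 239 and 3814. With the animal left out of the model they were 0 and 4. Against PMd, the adjusted p without animal 2 was 0.145 for SPP1, 0.248 for RFTN2, 0.269 for SLC25A17, 0.138 for NEFH, 0.138 for DIAPH3, 0.251 for FREM3, 0.248 for EPHA3, 1 for EGR2 and 0.601 for RBP4. Without animal 1 it was 0.0803 for SLC25A17 and 0.0984 for EGR2. Against PMv, UGT8 (0.0956), FREM3 (0.0626), SH2D4B (0.276) and RBP4 (0.216) did not pass without animal 2, nor UGT8 (0.141) and ANKRD6 (0.0507) without animal 1. Leaving out the 2 left PMv arrays whose log2 values spread least gave 343 calls for M1 minus PMd and 691 for M1 minus PMv.

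Both premotor areas were set against A46. SLC8A1 (1.52, SE 0.25), RFTN2 (1.47, SE 0.12), NEFH (1.42, SE 0.08) and SPP1 (1.31, SE 0.13) were higher in PMd, and TNNT2 (-0.63, SE 0.08), the follistatin-like FSTL5 (-0.6, SE 0.1), SLF1 (-0.6, SE 0.11) and CD53 (-0.58, SE 0.07; 2 of its 3 probe sets had this sign) lower. SLC8A1 (1.23, SE 0.25; 1 of its 2 probe sets had this sign), UGT8 (1.18, SE 0.2), LOC699434 (1.17, SE 0.2) and SPMIP7 (1.14, SE 0.18) were higher in PMv, and EGR2 (-0.91, SE 0.11), the semaphorin SEMA3C (-0.81, SE 0.11), CD53 (-0.78, SE 0.07) and FOS (-0.72, SE 0.1) lower. MBP was higher in PMd (0.74, adjusted p = 0.0138) and in PMv (0.82, adjusted p = 0.0135). PMd minus A46 called 367 probe sets higher and 148 lower, with cyclic loess between arrays 554 and 350, and with the spread of log2 values as a covariate 1317 and 1139. Without animal 3 the majority was lost (1513 and 1542). PMv minus A46 called 166 higher and 158 lower, a split that did not hold: it was 416 and 267 with cyclic loess, 425 and 266 without the 2 left PMv arrays, and 1910 and 5099 without animal 3. Without animal 1 the totals of 515 and 324 were 40 and 47, without animal 2 they were 12 and 1, without animal 3 they were 3055 and 7009, and with the animal left out of the model 8 and 1. In PMd minus A46 without animal 2, NEFH, RFTN2 and SPP1 passed and SLC8A1 (adjusted p = 0.355), TNNT2 (0.105), FSTL5 (0.503), SLF1 (0.423), CD53 (0.0654) and MBP (0.289) did not. Nor did SLC8A1 (0.161), TNNT2 (0.0545), SLF1 (0.136), CD53 (0.0681) and MBP (0.183) without animal 1. In PMv minus A46 without animal 2 the adjusted p was 0.247 for UGT8, LOC699434, SPMIP7, EGR2 and FOS, 0.963 for SLC8A1, 0.472 for SEMA3C, 0.0889 for CD53 and 0.354 for MBP. Without animal 1 it was 0.242 for SLC8A1, 0.122 for UGT8, 0.103 for LOC699434, 0.0573 for EGR2, 0.0869 for SEMA3C and 0.0904 for MBP. Without the 2 left PMv arrays whose log2 values spread least the totals were 1121 and 691. Those arrays come from animals 1 and 2, so without animal 3 every PMv mean held such an array.

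PMd and PMv differed in the calls of FOS, an immediate early gene, and DIAPH3. FOS was 1.74-fold higher in PMd (0.8, SE 0.1, adjusted p = 0.0307), at 7.84 ± 0.29 against 7.04 ± 0.3 (SD, n = 3 animals), and DIAPH3, an actin-nucleating formin in the layer 5 list, was 1.85-fold higher (0.89, SE 0.1, adjusted p = 0.0119). All 15 immediate early genes had a positive difference and 12 passed when adjusted over the list alone, although FOS was the 1 that passed among all probe sets: DUSP1 (0.5), ARC (0.48) and IER2 (0.44) each had an adjusted p = 0.257. The list's median was 0.42 (camera adjusted p = 2.46e-22, and adjusted p = 0.298 with an estimated correlation). The 22 mitochondrial genes also all had a positive difference, with 0 past limma's threshold (0 when adjusted over the list alone) and a median of 0.11 (camera adjusted p = 4.51e-06, and adjusted p = 0.382 with an estimated correlation). The median of all tested probe sets was itself 0.029. As means relative to all arrays, these genes stood at -0.19 and -0.17 on the left PMv arrays of animals 1 and 2, which have the narrowest spread. They stood at 0.03 on the right PMv array of each, and at 0.02 (left) and -0.08 (right) in animal 3. The 2 left arrays could thus account for a part of this shift. NEFH (0.45, adjusted p = 0.257) and PVALB (0.53, adjusted p = 0.297) did not pass, and oligodendrocyte genes had a median of 0.03 (camera adjusted p = 0.848). Smaller shifts were called for neurofilament (0.11, camera adjusted p = 0.00115), layer 6 (-0.05, 0.00213), motor or sensory-cortex (0.19, 0.00518), fast-firing (0.12, 0.00435), microglia (-0.03, 0.00736) and growth genes (0.09, 0.0161), with adjusted p = 0.358, 0.358, 0.358, 0.445, 0.47 and 0.512 with an estimated correlation. In each of these lists 0 members passed limma's threshold among all probe sets. On the same 2 left PMv arrays fast-firing genes stood at -0.27 and -0.2, against -0.13 and -0.04 on the right. Growth genes stood at -0.27 and -0.19 there, against -0.05 and -0.11 on the right. Without animal 3 layer 6 (adjusted p = 0.108), motor or sensory-cortex (0.189), fast-firing (0.0555) and microglia genes (0.0799) lost their calls. Growth genes lost theirs without animal 1 (0.0676) and animal 2 (0.097) and microglia without animal 1 (0.257).

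For PMd minus PMv 1425 of 26383 probe sets had an unadjusted limma p under 0.05, close to the share of 0.05 that no difference would give. FOS and DIAPH3 were the 2 calls. The count was 1 without animal 1, 0 without animal 2 and 1398 without animal 3, and 0 with the animal left out of the model. FOS did not pass without animal 1 (adjusted p = 0.205) or animal 2 (0.949). The FOS PMd minus PMv difference also did not pass with the spread of log2 values as a covariate (0.0725) or with only the brightest 25% of probe sets (0.0542). DIAPH3 did not pass without animal 2 (0.508). The left PMv arrays of animals 1 and 2 had the smallest SD of log2 values of all arrays, 1.79 and 1.83 in a range up to 1.95, and the actin 3' to 5' log2 ratio was 1.1 ± 0.14 in PMv and 0.99 ± 0.15 in PMd (SD, n = 3 animals). Without these 2 arrays the count was 2.

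**Figure D3:**
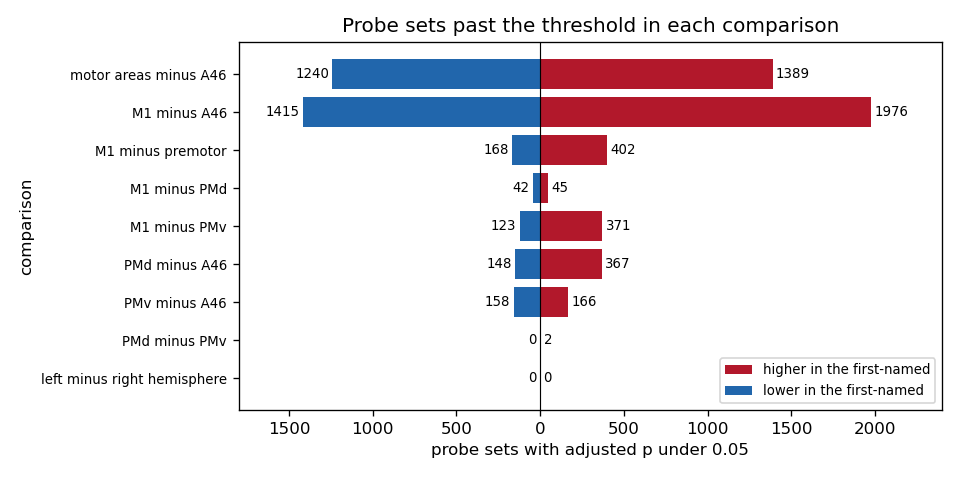
Number of probe sets with an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), higher (red, right) and lower (blue, left) in the first-named area or side. M1 minus A46 has the most calls, 1976 and 1415, and left minus right 0.

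Left and right hemispheres were compared within animal and area. The largest differences among the fixed genes were those of CUX2 (-0.17, SE 0.06, adjusted p = 0.537) and FEZF2 (0.12, SE 0.06, adjusted p = 0.642), and neither passed. NEFH (0.09, adjusted p = 0.769), SPP1 (0.06, adjusted p = 0.882) and MBP (0.04, adjusted p = 0.925) did not pass. Immediate early genes had a median of -0.06 on the left (camera adjusted p = 0.000608, and adjusted p = 0.438 with an estimated correlation), with 0 of 15 past the threshold and 1 when adjusted over the list alone. Medians of 0.06 or less in size were also called for microglia markers (-0.04, camera adjusted p = 0.023), endothelial markers (-0.04, 0.024), upper layer markers (-0.05, 0.0348) and oligodendrocyte genes (0.06, 0.0426). With an estimated correlation these had an adjusted p = 0.358, 0.477, 0.529 and 0.576, and each was lost without at least one animal: without animal 3 the adjusted p was 0.475, 0.294, 0.0766 and 0.81.

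With limma 0 probe sets passed for left minus right (smallest adjusted p = 0.346), while 2022 had an unadjusted p under 0.05; 252 passed with the spread of log2 values as a covariate (16 higher and 236 lower), 38 on per-animal means (1 higher and 37 lower) and 1 with cyclic loess between arrays. Tested within single areas, 1 probe set passed in PMd, that of the transcription factor MAX (0.68, adjusted p = 0.023), and 0 in A46, M1 and PMv, with 485, 501 and 3936 at an unadjusted p under 0.05 and 1059 in PMd. For the hemisphere by area interaction 0 probe sets passed (smallest adjusted p = 0.999, with 1113 at an unadjusted p under 0.05). With no difference a share of about 0.05 of the 26383 probe sets would have an unadjusted p under 0.05. The counts for A46, M1, PMd and the interaction lay below that share, and those for PMv and for left minus right above it.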

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

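The rule for single arrays was set before the values were seen, while the tests of the 2 left PMv arrays against actin, and the fits without them, were chosen only after the result was seen.

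FEZF2 stood at 8.89 on the left M1 array of animal 2, above the nearest of the other 5 M1 arrays at 8.57. HTR2A stood at 8.32 on the left A46 array of animal 1, with the nearest at 8.06. MBP stood at 12.97 on the right PMd array of animal 3, below the nearest at 13.33. These were 3 of 64 groups of 6 arrays, and about 1 group in 20 is singled out by chance with this rule, so 3 are no more than chance gives.

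The left PMv arrays of animals 1 and 2 had the narrowest spread of log2 values, 1.79 and 1.83. A scale difference that depends on intensity could be the cause and stays open. A smooth curve on intensity accounted for a share of 0.09 and 0.04 of the variance of left minus right on these arrays, and for 0.02 to 0.08 in the other 10 pairs. Both shares were below the bound set beforehand for excluding it, but that bound was a poor one, since 0.09 exceeded the share of every other pair. Degraded RNA could contribute, and the test left it open: the actin 3' to 5' log2 ratios were 1.16 and 1.02, and 4 other arrays were higher than 1.16, with the left PMd array of animal 1 equal to it when rounded, while 5 had been set for excluding degradation. The ratio of 1.02 lay inside the range of all arrays, 0.77 to 1.32.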

How the results depend on the processing

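The tests without the 2 left PMv arrays, those with the spread of log2 values as a covariate and cyclic loess for the gene lists were chosen only after the result was seen. Counts are probe sets past the threshold, and the cause of a change was not tested unless stated.

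With the brightest 25% of probe sets PMd minus PMv had 0 calls, and with no trend in eBayes M1 minus PMd had 50 (19 higher and 31 lower). Cyclic loess gave 896 for M1 minus premotor, 201 for M1 minus PMd, 772 for M1 minus PMv, 904 for PMd minus A46, 683 for PMv minus A46 and 1 for left minus right.

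With no replicate block, so without pairing by animal, the counts were 288 for any area difference, 479 for motor areas minus A46, 1056 for M1 minus A46, 11 for M1 minus premotor, 0 for M1 minus PMd, 4 for M1 minus PMv, 8 for PMd minus A46, 1 for PMv minus A46 and 0 for PMd minus PMv. The block removes the differences between animals, and dropping it changed no count for left minus right or the interaction.

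Hemispheres as samples gave, in the same order, 4768, 5266, 5717, 1460, 687, 1780, 2245, 2593 and 45 because this counts both arrays of an animal as replicates. Left arrays alone gave 526, 919, 1263, 31, 1, 32, 149, 105 and 0. Right arrays alone gave 214 for M1 minus PMd, 297 for M1 minus PMv, 133 for PMv minus A46 and 1 for PMd minus PMv. Only the areas compared gave 871 for M1 minus premotor, 1582 for M1 minus PMd, 1225 for M1 minus PMv, 92 for PMv minus A46 and 37 for PMd minus PMv. Per-animal means gave 38 for left minus right.

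Without the 2 left PMv arrays the counts were 2650 for any area difference, 864 for M1 minus premotor, 343 for M1 minus PMd, 1121 for PMd minus A46, 691 for PMv minus A46 and 7 for the interaction. M1 minus PMv also had 691 there, with the same 425 higher and 266 lower from a different set of probe sets. With the spread as a covariate the counts were 4201 (any area difference), 5718 (motor areas minus A46), 6519 (M1 minus A46), 1087 (M1 minus premotor), 668 (M1 minus PMd), 2456 (PMd minus A46), 685 (PMv minus A46), 1 (PMd minus PMv), 252 (left minus right, 16 higher and 236 lower) and 1 (interaction). The share higher was then 47.5% for M1 minus A46, 46.4% for M1 minus premotor and 38.6% for M1 minus PMv.

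Without animals 1, 2 and 3 in turn the counts were 609, 129 and 7754 for any area difference, 861, 180 and 6463 for motor areas minus A46. They were 1648, 403 and 5410 for M1 minus A46, 199, 25 and 1370 for M1 minus premotor, and 33, 0 and 239 for M1 minus PMd. They were 68, 21 and 3814 for M1 minus PMv, 40, 12 and 3055 for PMd minus A46. They were 47, 1 and 7009 for PMv minus A46, 1, 0 and 1398 for PMd minus PMv, and 0, 0 and 4 for the interaction. Without animal 3, 3166 of the 3391 calls for M1 minus A46 remained. The narrow-spread left PMv arrays come from animals 1 and 2, so without animal 3 every PMv mean held such an array. Leaving out animal 3 and the weight of those arrays cannot be told apart in the PMv counts.

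With an estimated correlation 0 of 115 gene list tests passed, against 44. Meninges and choroid plexus genes in PMd minus PMv, not called with all animals (median 0.01, adjusted p = 0.299, direction down), were called up without animal 1 (median 0.1, adjusted p = 0.0248) and down without animal 3 (-0.14, 0.00103).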

Other observations

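The tests of neurofilament genes against white matter, of a general rise of non-neuronal cells, and of immediate early genes against the left PMv arrays and actin were chosen only after the result was seen; the pan-neuronal test and the regroupings of samples were set before.

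Among cortical patterning genes 4 transcription factors were lower in M1 than in A46, although the list as a whole was not called: BHLHE22 (-0.71, SE 0.1, adjusted p = 0.000625), the retinoic acid receptor RARB (-0.62, SE 0.09, adjusted p = 0.000714), TSHZ3 (-0.56, SE 0.07, adjusted p = 0.00031) and NR2F1 (-0.4, SE 0.08, adjusted p = 0.00554), the last with 0.116 without animal 2. Of 18 tested patterning and retinoic acid genes 5 fell and 1 rose (6 and 2 when adjusted over the list alone; median -0.06, camera adjusted p = 0.0766), and the list passed without animal 2 (0.0357). The neurotrophin BDNF (-0.5, adjusted p = 0.0103; 1 of its 2 probe sets had this sign), the adhesion molecule L1CAM (-0.31, adjusted p = 0.0194) and the neurotrophin receptor NTRK3 (-0.26, adjusted p = 0.0148) were lower and STMN2 (0.25, adjusted p = 0.0135) higher. None of these 4 passed without animal 2 (0.343, 0.459, 0.355 and 0.255) or animal 1 (0.0634, 0.1, 0.146 and 0.148). Of 13 growth and plasticity genes 5 fell and 2 rose, the same when adjusted over the list alone (median -0.13, camera adjusted p = 0.134, and 0.038 without animal 3).

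Interneuron markers moved both ways, and their list was not called. CRH (0.85, SE 0.1, adjusted p = 0.00012) and the GABA-synthesising enzyme GAD2 (0.78, SE 0.13, adjusted p = 0.00133) were higher in M1 than in A46 with PVALB, and the neuropeptide VIP was lower (-0.48, SE 0.09, adjusted p = 0.00399). GAD2 (0.0686) and VIP (0.189) did not pass without animal 2. Of 12 GABAergic markers 4 rose and 2 fell, the same when adjusted over the list alone, with a median of 0 and a mean of 0.19 (camera adjusted p = 0.54). Among 5 GABA receptor genes GABRB1 was lower (-0.48, adjusted p = 0.0033) and GABRE higher (0.41, adjusted p = 0.0243), with 2 lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.303). Of 17 monoamine and acetylcholine receptor genes the muscarinic receptors CHRM3 (-0.33, adjusted p = 0.0109) and CHRM1 (-0.27, adjusted p = 0.0319) and the serotonin receptor HTR3A (-0.39, adjusted p = 0.0304) were lower and the adrenergic receptor ADRA1A (0.44, adjusted p = 0.0306) higher, the same when adjusted over the list alone (median -0.07, camera adjusted p = 0.0766). Without animal 2 the adjusted p was 0.161 for GABRB1, 0.474 for GABRE, 0.276 for CHRM3, 0.368 for CHRM1, 0.521 for HTR3A and 0.305 for ADRA1A. Without animal 1 it was 0.0523, 0.0795, 0.0945, 0.128 and 0.093 for the first 5, and without animal 3 it was 0.149 for ADRA1A.

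Myelin and neurofilament genes were both higher in M1, and a deeper piece with more white matter could raise the first. That explanation stays open for oligodendrocyte genes: the median of 17 pan-neuronal genes was -0.05, and it was negative in each animal (-0.11, -0.1 and -0.05), which goes with dilution by white matter. The test asked only for the sign and is weak, since 4 of the 17 genes lay above 0. The median of all tested probe sets was itself -0.011. Whether white matter also raised leading genes outside the oligodendrocyte list, such as EVI2A, ANLN, TMEM144 and DOCK5, was not tested. A general rise of non-neuronal cells would raise astrocyte and microglia markers by about as much. The oligodendrocyte mean exceeded theirs by 1.1 (1.09, 1.38 and 0.84 in the 3 animals), which argues against such a rise. This gap restates list differences that were known when the test was chosen. White matter would dilute neuronal transcripts, which argues against it as the source of the rise of NEFH (2.24) and VAMP1 (0.74). The neurofilament list mean of 0.73 (0.71, 0.76 and 0.71) restates that rise and is carried by NEFH and SPP1, with a median of 0.24.

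Immediate early genes were lower as a list in PMv than in PMd, with 1 of 15 (FOS) past limma's threshold. Camera with an estimated correlation gave the list an adjusted p = 0.298. The 2 left PMv arrays do not account for all of the difference. On right-hemisphere arrays alone the list median was 0.31, with 0.3 and 0.55 in animals 1 and 2, which hold those arrays, and 0.18 in animal 3, which holds neither. The bound of 0.2 was first set for all 3 animals and was limited to animals 1 and 2 after these values were seen. Without the 2 arrays the median was 0.35, against 0.42 with them, so they could account for a part. Degradation is undecided. The actin ratio of M1, which has low immediate early gene levels, was below that of A46 in all 3 animals (-0.24, -0.12 and -0.06). That is against the direction degradation would give, but the GAPDH ratio was higher in M1 (0.96) than in A46 (0.84). The actin ratio of M1 was below that of PMd on average (-0.05) but not in animal 3 (0.09). PMv lay above PMd in the actin ratio by 0.11, the direction degradation would give. Between these 2 areas the GAPDH ratio went the other way, 0.92 ± 0.06 in PMv and 0.95 ± 0.06 in PMd (SD, n = 3 animals).

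Regrouping the samples gave counts to compare with the real ones, each count including the real grouping. For motor areas minus A46, 3 of 100 groupings gave at least the 2629 real calls, up to 3328; for M1 minus premotor 1 of 84 did (570 calls, at most 40 in the others); for any area difference 1 of 100 did (1723, at most 169). Groupings that keep 1 mean per animal are the fairer comparison, since those across animals gave at most 0 and 3 calls: within animals it was 3 of 64 for motor areas minus A46 and 1 of 27 for M1 minus premotor. For left minus right and for the interaction all 100 of 100 did, since both had 0 calls. With 3 means against 3 there are 10 groupings, too few to exclude chance: 1 of 10 for M1 minus A46 (3391 calls), M1 minus PMd (87), M1 minus PMv (494), PMd minus A46 (515) and PMd minus PMv (2), with 0 in every other grouping, and 2 of 10 for PMv minus A46 (324, at most 4063 in the others). Of those 10, 4 keep the animals paired.

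Exchanging PMv and A46 of animal 3 gave 4063 calls, more than the 324 as labelled, and a swapped label could do this. NEFH argues against it: PMv minus A46 was 0.83, 1.17 and 0.9 in animals 1, 2 and 3. SPP1 (0.84, 1.63 and 0.77), fixed by name beforehand like NEFH, also kept its sign in animal 3. RFTN2 (0.95, 1.34 and 0.68) did too, but is weaker evidence. The naming rule picked it for large differences from A46 in the same direction in all 3 animals. Without the 2 left PMv arrays the exchange gave 718 calls against 691 as labelled, so the excess rests mostly on those arrays. For left minus right, the regrouping with 2386 calls put the array with the wider spread on the same side in 11 of 12 pairs.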
